A study of Homo sapiens with 24 samples.

How the data were processed

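RNA was measured by sequencing in human umbilical vein endothelial cells (HUVECs), the cells that line the vein of the umbilical cord. Per the labels' protocols, passage 1 cells were freshly isolated and pooled from 3 umbilical cords, and passage 10 cells were obtained commercially. Passage number and cell source therefore change together in every comparison of passages. At each passage, 4 libraries were controls, 4 came from cells given cycloheximide (CHX) at 100 µg/ml for 5 min, and 4 came from cells given homoharringtonine (HHT) at 2 µg/ml for 5 min. CHX blocks the movement of ribosomes during elongation, and HHT blocks the first steps of elongation after initiation. The labels do not say whether controls received a vehicle, nor what the replicate numbers mark. An isolation-method label of fresh cells stands on passage 10 samples too and disagrees with the commercial origin given in the protocol. RNA was purified on columns, turned into cDNA with a SMART-Seq V4 kit and made into libraries with a Kapa HyperPrep kit, per the labels' protocols. A kit of this kind does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

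The deposited values are FPKM, fragments per kilobase of transcript scaled to sequencing depth, for 58721 genes in each of 24 libraries. The submitters' processing notes name bcl2fastq, Bowtie2 2.2.3 and genome build GRCh38.p12. The tool that turned alignments into FPKM, and how it treated reads shared by several genes, are not given in the sources used here. All 58721 gene identifiers matched the GENCODE 29 annotation, which gave symbols and coordinates. The 24 files of single libraries were identical to the columns of the joint table. In genes with 1 annotated transcript, low values corresponded to whole reads when the transcript length minus 24 bases was used as the effective length. This held for 100% of the 963 to 1245 values examined per library, up to 30 reads and with a tolerance of 0.05 reads. The implied depth was 690204 to 1073224 reads per library, so that 1 read on a transcript of 2000 bases was worth 0.466 to 0.724 FPKM. FPKM totals ranged from 436541 to 493799. Genes of a few FPKM thus rest on a handful of reads, and a value of 0 means that no read was assigned at this depth.

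From the table, 610 entries were left out, being 45 identifiers listed 2 times (90 entries), the Y chromosome, and the transcripts of X inactivation. FPKM values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with trended and robust variance estimates, over all 24 libraries in 1 model with a mean per group. Genes with at least 1 FPKM in at least 4 libraries entered, which left 13645. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called below 0.05. The planned test assumed counts and named limma-trend as the choice for normalized values. The count-based alternatives could not be run since the files hold no counts. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and carry a standard error (SE). Group values are mean FPKM ± SD over n = 4 libraries unless another number is given. Where a gene was at 0 in all libraries of a group, it is given as listed at 0 with no fold change. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

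Comparisons were each inhibitor against control at each passage, passage 10 against passage 1 within each treatment, HHT against CHX over both passages, and the interaction of each inhibitor with passage. The labels do not say that libraries are from separate cultures, so p-values measure the spread between these samples, which may be technical. These comparisons, the tests, 31 gene lists, the rule for named genes and the alternatives below were fixed before the data were examined. Of the lists, 30 had tested members, 701 of 784 different genes. They were immediate early genes, NF-kB and cytokine response, integrated stress response, unfolded protein response, heat shock response, snoRNA hosts with known nonsense-mediated decay targets, cytosolic ribosomal proteins, translation factors, mitochondrially encoded transcripts, and nuclear oxidative phosphorylation genes. Endothelial lists covered pan-endothelial identity, coagulation and fibrinolysis, arterial identity and Notch, venous and lymphatic identity, tip cell and angiogenesis, the flow-responsive KLF2 and KLF4 programme, BMP and TGF-beta targets, endothelial-to-mesenchymal transition, and extracellular matrix. The rest were S phase, G2 and M phase, senescence and p53, interferon-stimulated genes, cholesterol synthesis and uptake, glycolysis and hypoxia, replication-dependent histones, and markers of smooth muscle, fibroblast, leukocyte, erythroid and epithelial cells. All 16 erythroid markers were listed at 0 in every library, so that list was not tested.

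Lists were tested against all other genes with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists in each comparison. Camera with a correlation estimated for each list was run beside it, as was fry. The PValue of fry tests whether the genes of a list move on balance in 1 direction, and its mixed p-value whether they change in either direction. Neither fry value compares a list with other genes. Members past the threshold were counted over all genes and also adjusted over the list alone.

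The rule for named genes takes genes past the threshold with a symbol, a mean of at least 5 FPKM in a compared group and no overlap between the libraries of both groups, and keeps the 10 largest changes in each direction. Where fewer than 3 genes passed, those with the smallest p in each direction were given as values. Members of each list were taken in order of adjusted p, and where none passed, those with the highest mean. The rule was written for counts scaled to depth and was applied to FPKM, and the text names the first members it gives, a narrowing made after values were seen. Of the genes it gives, 2 are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

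The alternatives fixed in advance were a pseudocount of 0.1, no filter, a stricter filter, a model of the compared groups alone, an added fold-change limit, the replicate number as a block, and leaving out each library. After the data were seen, 4 more were added, namely median-of-ratios scaling over 9904 genes, removal of PTP4A2 and SENP3, library weights, and removal of both passage 1 control libraries high in MT-CO1. The procedure was tested on simulated counts with 200 changed genes, drawn at the depths and means of these libraries with a dispersion of 0.02. Over genes with a mean of at least 10 FPKM, the median residual SD was 0.291 in the real libraries and 0.3 in the simulated ones. The dispersion was chosen on these genes, and the match was not examined for lower genes. For CHX against control at passage 1, simulated over 13305 genes, 7.5% of 1.5-fold, 38.8% of 2-fold and 72.7% of 4-fold changes were called. Among genes with a mean of at least 10 FPKM these shares were 12.8%, 68.8% and 100%. In that simulation 82 genes were called, 3 of them unchanged. In the simulations of the other comparisons, the unchanged share ran from 2 of 106 (HHT against CHX) to 7 of 82 (HHT at passage 1). It was 6 of 79 for HHT at passage 10 and 7 of 93 for passage in controls.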

Results

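The series holds RNA levels in human umbilical vein endothelial cells at passage 1 and passage 10, each as controls and after 5 min with 1 of 2 inhibitors of translation, cycloheximide (CHX) or homoharringtonine (HHT). There were 6 groups of 4 libraries. Both inhibitors block ribosomes at steps of elongation, and the comparisons against control ask whether so brief an exposure alters total RNA levels. The comparisons of passages ask how freshly isolated cells differ from commercially obtained cells kept to passage 10. Mean implied depth was 978000 ± 121000 reads in passage 1 controls and 844000 ± 135000 in passage 10 controls. With CHX it was 913000 ± 164000 and 801000 ± 64000, and with HHT 913000 ± 117000 and 739000 ± 47000 (SD, n = 4). Between 12810 and 13692 genes were above 0 per library.

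Passage set the main division between libraries. The first principal component of the 13645 tested genes carried 39.7% of the variance and separated all passage 1 from all passage 10 libraries, while the second carried 4.3%. Within groups, libraries correlated across genes with r between 0.93 and 0.956. In each of the 36 pairs of replicates the implied read counts differed by more than counting noise, with a chi-square per degree of freedom of 1.223 to 5.393, so no pair was taken for 1 library deposited in duplicate. Whether the libraries came from separate cultures is not shown by this. PTP4A2 and SENP3 were the highest genes of every library, at 10142 to 36418 and 6246.4 to 22053 FPKM, and together took 3.33% to 12.8% of all FPKM. Mitochondrially encoded transcripts made up 2.127%, 1.954% and 2.197% of FPKM in control, CHX and HHT libraries at passage 1, and 1.662%, 1.682% and 2.04% at passage 10.

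**Figure D1:**
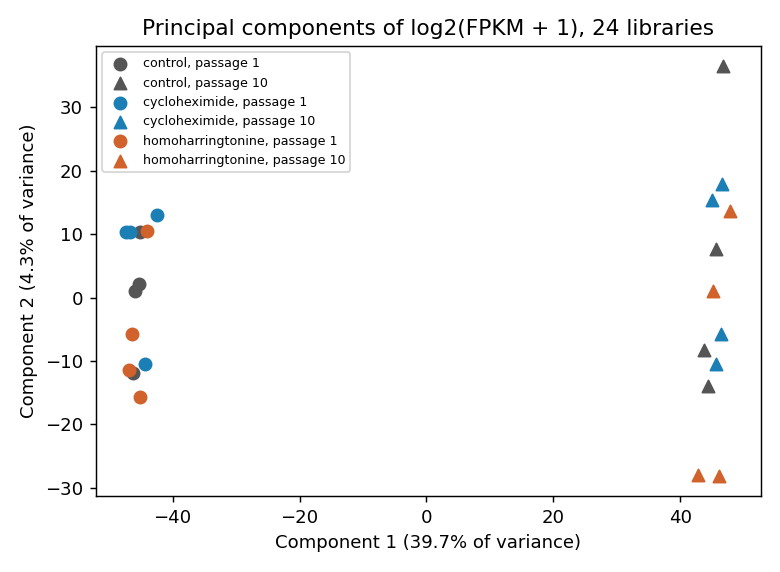
Principal components of log2(FPKM + 1) over 13645 genes, with 1 point per library and 4 libraries per group. The horizontal axis is component 1 (39.7% of the variance), on which passage 1 and passage 10 libraries lie apart, and the vertical axis is component 2 (4.3%); con is control, CHX cycloheximide and HHT homoharringtonine.

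At passage 1, immediate early genes, whose transcripts can accumulate when translation is blocked, lay near their control levels with CHX. CCN2, a target of the YAP pathway, was at 660 ± 73.5 FPKM in controls and 688 ± 61.3 with CHX, and CCN1 at 481 ± 26.8 and 483 ± 32. No gene passed the adjusted threshold in limma, and 585 of 13645 had an unadjusted p under 0.05 (4.29%), with a smallest adjusted p of 0.12. Among values that did not pass, IDE, which encodes a protease that degrades insulin, was 0.78 ± 0.16 (log2, SE) above control, at 22.1 ± 3.83 and 38.4 ± 4.29 FPKM (adjusted p = 0.343). ALG14, an enzyme subunit of N-glycan assembly, was at 0.708 ± 0.406 and 7.87 ± 3.31 FPKM, and TRA2A, a splicing regulator, at 27.1 ± 4.77 and 43.1 ± 6.25. CRCP was at 16.6 ± 3.1 and 6.78 ± 2.42 FPKM, PROSER1 at 23.7 ± 2.69 and 13.4 ± 2.02, and MT-ND6, a subunit of respiratory complex I, at 171 ± 40.7 and 93.7 ± 29.1.

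Of the 30 gene lists tested at passage 1, 2 shifted upward with CHX relative to other genes. The 85 cytosolic ribosomal protein genes had a median log2 fold change of 0.18 (camera adjusted p = 5.69e-07; adjusted p = 0.991 with an estimated correlation). Without CHX passage 1 replicate 3 the adjusted p of this list was 0.132. Changes of single members ranged from -0.22 to 1.31, and of those with the highest means, RPL3 was at 698 ± 41.9 FPKM in controls and 695 ± 115 with CHX, and RPLP0 at 379 ± 29.5 and 379 ± 54.7. The 39 interferon-stimulated genes had a median of 0.16 (camera adjusted p = 6.31e-05; adjusted p = 0.413 with an estimated correlation), and a mixed adjusted p of 0.0203 in fry. Changes of single members ranged from -0.64 to 1.58, and those with the highest means moved little, B2M being at 1230 ± 83.5 and 1370 ± 163 FPKM and HLA-E at 153 ± 9.3 and 162 ± 6.87. No member of either list was past the threshold over all genes or adjusted over the list alone. Adjusted over the list alone, 2 mitochondrially encoded transcripts, 1 BMP and TGF-beta target and 1 endothelial-to-mesenchymal transition gene were lower. The mitochondrial ones, named after their values were seen, were MT-ND6 and MT-CO1. MT-CO1 was at 1635 and 1455 FPKM in control passage 1 replicates 3 and 4 but at 339.8 and 328.4 in replicates 1 and 2. The median of the 24 immediate early genes was 0.02 (camera adjusted p = 0.987), that of the integrated stress response 0.03 (0.782), of the unfolded protein response 0.03 (0.781) and of snoRNA hosts with decay targets 0.04 (0.782).

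For 66.3% of tested genes the 95% interval of the CHX effect at passage 1 lay inside a 2-fold change either way, and for 91.2% of the 6865 genes with a mean of at least 10 FPKM. Groups without overlap between their libraries were found for 359 genes (2.63%), against 2.86% by chance.

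At passage 10, CHX again gave values close to control in the immediate early genes. CCN2 was at 3300 ± 370 FPKM in controls and 3010 ± 207 with CHX, and CCN1 at 952 ± 151 and 855 ± 110. No gene passed in limma, and 821 genes (6.02%) had an unadjusted p under 0.05, with a smallest adjusted p of 0.267. FAM172A was 0.91 ± 0.19 above control on the log2 scale, at 8.44 ± 2.03 and 16.5 ± 2.03 FPKM (adjusted p = 0.267). RAC2, a small GTPase, was at 12.6 and 23.5 FPKM (0.8 ± 0.19), and EIF5, an initiation factor, at 139 and 192 (0.47 ± 0.12). NUBPL, an assembly factor of respiratory complex I, was at 13 ± 1.77 and 3.79 ± 0.523 FPKM (-1.54 ± 0.3), TMUB1 at 37 ± 4.75 and 23.3 ± 3.42, and the ribosomal protein gene RPL39 at 35.9 and 14.4 (-1.51 ± 0.35). RAC2 passed when CHX passage 10 replicate 2 was left out (adjusted p = 0.0322), as did RASGRP3 (0.0385), and PTGES3P1 without control passage 10 replicate 2 (0.00111); these were chosen after their values were seen.

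Interferon-stimulated genes were the 1 list past camera with CHX at passage 10, with a median of 0.16 (adjusted p = 0.00288; adjusted p = 0.491 with an estimated correlation). Their mixed adjusted p in fry was 0.0228, and 2 members were higher adjusted over the list alone against none over all genes. The list was not past camera without CHX passage 10 replicate 3 (0.172). Changes of single members ranged from -0.56 to 1.76, with B2M, of the highest mean, at 1280 ± 118 FPKM in controls and 1400 ± 118 with CHX. Cholesterol synthesis genes had a median of -0.05 and a mixed adjusted p of 0.00208, with 1 member higher and 2 lower adjusted over the list alone. FDFT1, which makes squalene, was at 60.4 ± 9.39 and 48.3 ± 5.14 FPKM. Ribosomal protein genes had a median of 0.05, a mean of -0.02 and an upward test (camera adjusted p = 0.722), with 1 member higher and 2 lower adjusted over the list alone. Medians were -0.06 for immediate early genes (0.404), -0.06 for the integrated stress response (0.722) and -0.01 for the unfolded protein response (1).

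The interval of the CHX effect at passage 10 lay inside a 2-fold change for 64.3% of genes and for 90.7% of those with a mean of at least 10 FPKM. Non-overlapping libraries were seen in 359 genes (2.63%, chance 2.86%), and CHX fold changes at both passages correlated across genes, which are not independent replicates, with r = 0.046.

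At passage 1, HHT gave control-like levels of CCN2 (660 ± 73.5 and 618 ± 111 FPKM) and CCN1 (481 ± 26.8 and 479 ± 37.2). In limma 0 genes passed, 531 (3.89%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.12. MGARP, a mitochondrial protein of steroid-making cells, was at 16.8 and 26.3 FPKM (0.61 ± 0.15, adjusted p = 0.645), CYBA, a subunit of NADPH oxidase, at 5.9 and 15.8 (1.32 ± 0.32), and HMGB1, a chromatin protein, at 116 and 155 (0.4 ± 0.1). SEC63, part of the protein translocation machinery of the endoplasmic reticulum, was at 58.5 and 29.3 FPKM (-0.94 ± 0.21), USP7, a deubiquitinase, at 16.9 and 6.41 (-1.35 ± 0.33) and PRR11 at 19.7 and 10.9 (-0.8 ± 0.21). BCL3 and CKB passed without HHT passage 1 replicate 4 (adjusted p = 0.0436 for each, chosen after their values were seen). Mitochondrially encoded transcripts were the 1 list past camera, with a median of 0.18 and a mean of 0.09 (adjusted p = 0.0131; adjusted p = 0.881 with an estimated correlation). It had 1 member higher adjusted over the list alone and none over all genes. The list was not past camera without control passage 1 replicate 1 (0.151) or 2 (0.255) or without HHT passage 1 replicate 2 (0.162). MT-RNR2, the large ribosomal RNA of mitochondria, was at 4370 ± 268 FPKM in controls and 4780 ± 25.3 with HHT. Immediate early genes had a median of -0.07 (0.395), the integrated stress response -0.02 (0.796) and the unfolded protein response 0.04 (0.557). For 66.1% of genes, and 91% of those with a mean of at least 10 FPKM, the interval lay inside a 2-fold change; 352 genes had non-overlapping libraries (2.58%, chance 2.86%).

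At passage 10, MT-ATP6, a subunit of mitochondrial ATP synthase, rose with HHT from 260 ± 11.8 to 383 ± 44.8 FPKM, a 1.47-fold change (log2 0.55 ± 0.09, limma adjusted p = 0.0289, n = 4). MT-ATP6 (ENSG00000198899, chromosome M 8527 to 9207, GRCh38.p12) was the 1 gene that passed, while 989 (7.25%) had an unadjusted p under 0.05. MT-CO2, a subunit of cytochrome oxidase, was at 496 ± 68.6 FPKM in controls and 717 ± 84.9 with HHT (0.53 ± 0.11, adjusted p = 0.161). MT-ND4, of respiratory complex I, was at 492 ± 7.9 and 643 ± 62.8 (0.38 ± 0.08, adjusted p = 0.161), MT-CYB at 817 ± 76.9 and 994 ± 120 and MT-RNR2 at 3370 ± 368 and 4130 ± 470. The MT-ATP6 gene overlaps MT-ATP8 and has copies in the nuclear genome, and how shared reads were assigned is not given in the sources used here. The nuclear copy MTATP6P1, named after its values were seen, was at 65.65 FPKM in controls and 108.5 with HHT (0.72 ± 0.19, limma adjusted p = 0.327).

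The 15 mitochondrially encoded transcripts moved upward as a list with HHT at passage 10, with a median of 0.36 (camera adjusted p = 7.17e-14; adjusted p = 0.2 with an estimated correlation). Of them, 8 were higher adjusted over the list alone, against 1 over all genes, and fry gave an adjusted p of 0.149. Ribosomal protein genes had a median of 0.1 (camera adjusted p = 0.0154; adjusted p = 0.905 with an estimated correlation). RPLP0 was at 295 ± 36.2 FPKM in controls and 316 ± 39.2 with HHT, and RPL3 at 464 ± 46.9 and 441 ± 42.9. Interferon-stimulated genes had a median of 0.17 (camera adjusted p = 0.0186; adjusted p = 0.408 with an estimated correlation). No ribosomal protein or interferon-stimulated gene passed over all genes or adjusted over the list alone. Among genes that did not pass, YY1AP1 was at 13.4 and 29.9 FPKM (1.07 ± 0.22, adjusted p = 0.161), POMK at 7.88 and 2.61 (-1.33 ± 0.28), UACA at 31.5 and 18 (-0.79 ± 0.17) and the focal adhesion kinase gene PTK2 at 88.3 and 59.6 (-0.55 ± 0.12). Immediate early genes had a median of -0.1 (0.243), with CCN2 at 3300 ± 370 and 3050 ± 173 FPKM. The integrated stress response had a median of -0.02 (mean 0.02, downward test, 0.921) and the unfolded protein response -0.02 (0.935).

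The MT-ATP6 call ended in a model of the compared groups alone (adjusted p = 0.503), with no filter (0.0723) and with library weights (0.0519), while its log2 fold change lay between 0.5 and 0.63 in all settings. It also ended without control passage 10 replicate 2 (0.124), 3 (0.103) or 4 (0.122) and without HHT passage 10 replicate 2 (0.0722), 3 (0.123) or 4 (0.201). Without control passage 10 replicate 1, 3 genes passed, MT-ATP6, SAP30BP and ZNF24TR, and without HHT passage 10 replicate 1, 4 did, MT-ATP6, YY1AP1, MT-ND4 and BMS1P12; these were chosen after their values were seen. Ribosomal protein genes were not past camera without control passage 10 replicate 2 (0.164) or 4 (0.0638) or HHT passage 10 replicate 2 (0.152) or 3 (0.378). Interferon-stimulated genes were not past it without control passage 10 replicate 2 (0.053) or 4 (0.0638) or HHT passage 10 replicate 1 (0.0949), 2 (0.0737) or 4 (0.0514). The interval lay inside a 2-fold change for 63.3% of genes and 89% of those with a mean of at least 10 FPKM, and 381 genes had non-overlapping libraries (2.79%, chance 2.86%).

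**Figure D2:**
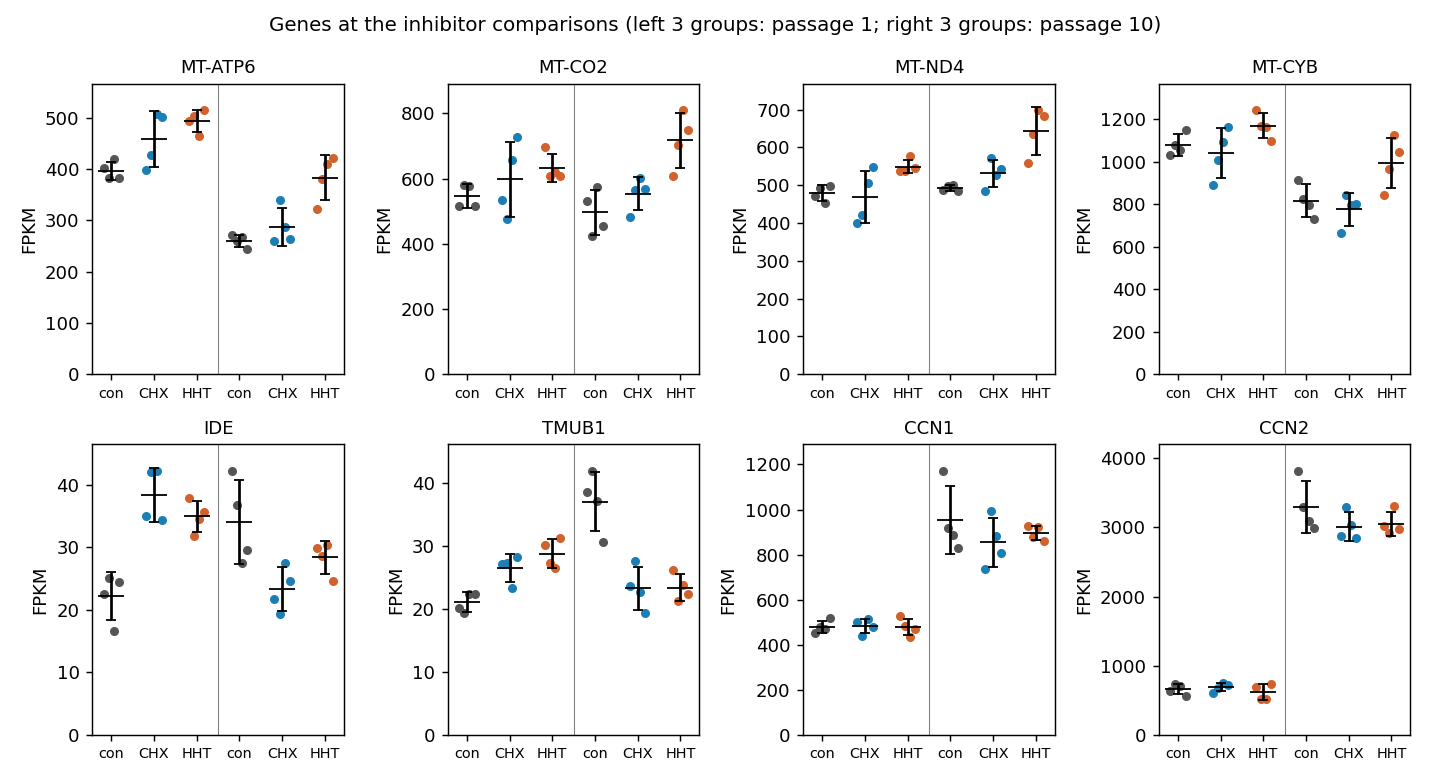
FPKM of 8 genes in each library by group, with passage 1 and passage 10 on the horizontal axis for control (con), cycloheximide (CHX) and homoharringtonine (HHT); points are libraries, dashes means and bars SD (n = 4), and the vertical axes start at 0. At passage 10, MT-ATP6 lay at 260 ± 11.8 FPKM in controls and 383 ± 44.8 with HHT, while CCN2 lay at 3300 ± 370 and 3050 ± 173.

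Mitochondrially encoded transcripts were the 1 list past camera between HHT and CHX over both passages, and 0 lists passed with an estimated correlation or in directional fry. Their median difference was 0.25 on the log2 scale, higher with HHT (camera adjusted p = 1.26e-14; adjusted p = 0.167 with an estimated correlation), and 8 of 15 were higher adjusted over the list alone and none over all genes. MT-ND4 was 0.26 ± 0.06 and MT-CYB 0.26 ± 0.06 above CHX (adjusted p = 0.455 for each). No gene passed in limma, with 803 at an unadjusted p under 0.05 (5.88%) and a smallest adjusted p of 0.142. INO80, a chromatin remodeller, was 0.95 ± 0.23 above CHX, and CASK (-1.12 ± 0.27), ADARB1 (-1.13 ± 0.29) and NAGLU (-0.88 ± 0.23) were below. SPACA6 passed without HHT passage 1 replicate 1 (adjusted p = 0.00896) or HHT passage 10 replicate 3 (0.016), and NAGLU (0.0402) and CKB (0.0486) without HHT passage 1 replicate 4; these were chosen after their values were seen. The interval of the difference lay inside 2-fold for 86.3% of genes and for 97.4% of those with a mean of at least 10 FPKM.

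The effects of both inhibitors against the same controls correlated across genes with r = 0.46 at passage 1 and 0.48 at passage 10. For comparison, unchanged groups were drawn from the deviations of all 24 libraries from their group means, with 4 drawn libraries as shared controls. The run set beside each passage gave 0.5, with a range over 100 draws of 0.2 to 0.74 and of 0.13 to 0.67. Neither run was limited to the libraries of its passage. With the controls split so that each inhibitor had its own, the mean r over 6 splits was -0.01 and 0.01. The covariance was 0.053 against a simulated 0.067 at passage 1, a difference of -0.015, and 0.067 against 0.065 at passage 10, a difference of 0.002. No gene was called for both inhibitors.

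The interaction of CHX with passage had its smallest p in IDE, which was above control at passage 1 (22.1 ± 3.83 and 38.4 ± 4.29 FPKM) and below it at passage 10 (34 ± 6.73 and 23.3 ± 3.5). The difference between passages was -1.29 ± 0.23 (limma adjusted p = 0.0715). It passed when control passage 10 replicate 3 was left out (0.0404) and with a stricter filter (0.0456). TMUB1, a membrane protein with a ubiquitin-like domain, had a CHX interaction of -0.97 ± 0.2 (adjusted p = 0.357) and an HHT interaction of -1.07 ± 0.2 (adjusted p = 0.188). Its levels were 21 ± 1.57, 26.4 ± 2.17 and 28.7 ± 2.26 FPKM in control, CHX and HHT libraries at passage 1, and 37 ± 4.75, 23.3 ± 3.42 and 23.4 ± 2.09 at passage 10. No gene passed for either interaction, with 651 (4.77%) and 653 (4.79%) at an unadjusted p under 0.05. Other CHX interactions that did not pass were ATP2A3 (2.04 ± 0.47), GTF2H3 (1.12 ± 0.28) and GSTM2 (-2.78 ± 0.63). For HHT they were SDSL (1.62 ± 0.39), MED18 (1.94 ± 0.49), SYNE1 (-1.35 ± 0.34) and CASP6 (-0.97 ± 0.24).

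Among lists, mitochondrially encoded transcripts differed between passages in their response to HHT, with a median interaction of 0.21 (camera adjusted p = 0.000517; adjusted p = 0.947 with an estimated correlation). Without both passage 1 control libraries high in MT-CO1 the adjusted p was 0.0661. Ribosomal protein genes had a CHX interaction with a median of -0.14 (camera adjusted p = 0.0545). At the preset correlation the list passed without control passage 1 replicate 1 (0.0138) or 3 (0.0259) or control passage 10 replicate 2 (0.00721). It also passed without CHX passage 1 replicate 1 (0.000555) or 2 (0.000184), or CHX passage 10 replicate 2 (0.0107) or 3 (0.0218). Over all libraries, 0 lists passed for the CHX interaction with an estimated correlation or in fry. The interval lay inside 2-fold for 39% of genes for CHX and 38.7% for HHT, and in the simulation of the CHX interaction over 13287 genes 7.5% of 2-fold interactions were called, and 13.5% among genes with a mean of at least 10 FPKM. Most interactions of that size were thus missed in the simulation.

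Between passage 1 and passage 10, VCAM1, an adhesion receptor for leukocytes, rose in control cells from 0.844 ± 0.12 to 158 ± 17.6 FPKM (n = 4; log2 6.43 ± 0.25, limma adjusted p = 1.14e-16). SULF1, a sulfatase of heparan sulfate, rose from 5.97 ± 2.66 to 906 ± 28, and TAGLN, an actin-binding protein of smooth muscle, from 8.59 ± 5.98 to 490 ± 30.1. LYVE1, a hyaluronan receptor of lymphatic endothelium, fell from 105 ± 19 to 0.558 ± 0.695, and KDR, the main receptor for VEGF, from 63 ± 8.93 to 3.69 ± 0.624. EFEMP1, a matrix glycoprotein, had the smallest p and rose 11.3-fold from 467 ± 16.8 to 5270 ± 346 FPKM (adjusted p = 4.38e-26). Passage 10 cells came from another source than passage 1 cells, so these differences are between cell preparations that differ in both.

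In limma 2811 of 13645 genes passed, 1156 higher at passage 10 (41.1%) and 1655 lower, and 1552 of them changed at least 2-fold (754 higher, 798 lower). An unadjusted p under 0.05 was found for 4195 genes, and 3018 genes had non-overlapping libraries (22.1%, chance 2.86%). The median log2 fold change over all genes was -0.08, and 0.009 after median-of-ratios scaling, which gave 2686 genes with 1393 higher (51.9%) and 1293 lower. With CHX the median moved from -0.117 to 0.008 and with HHT from -0.1 to 0.008. No list past camera changed direction under that scaling.

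The largest rises after SULF1 (chromosome 8, 69466624 to 69660915, GRCh38.p12) were in LITAF (6.67 ± 0.3, from 0.328 ± 0.423 to 132 ± 28.6 FPKM), VCAM1 (chromosome 1, 100719742 to 100739045) and CPE, a carboxypeptidase of hormone processing (6.31 ± 0.39, from 1.76 to 174). They were followed by TAGLN (5.92 ± 0.3; chromosome 11, 117199321 to 117204782), GBP4 (5.7 ± 0.33), the cadherin CDH11 (5.66 ± 0.31, from 2.57 to 180), ACKR3, a scavenger receptor for CXCL12 (5.62 ± 0.19, from 6.48 to 347), CPXM2 (5.58 ± 0.21) and the estrogen sulfotransferase SULT1E1 (5.51 ± 0.32). Among falls, CYTL1 (chromosome 4, 5014586 to 5019472) was at 118 ± 10.7 FPKM and listed at 0 in all passage 10 libraries. LYVE1 (chromosome 11, 10556966 to 10611689) fell by 6.17 on the log2 scale, LIPG, endothelial lipase, by 5.69 and KRT19, a keratin, by 5.18. ADTRP, a regulator of tissue factor pathway inhibitor, fell by 5.06, the hyaluronan receptor CD44 by 5.05 (162 ± 24.9 to 4.03 ± 1.34 FPKM), G0S2 by 4.77, the lincRNA MIR217HG by 4.77 and TNFSF4 by 4.55. TRBC2, a T cell receptor constant segment, fell by 5.67; its sequence is close to that of TRBC1, and how shared reads were assigned is not given in the sources used here.

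**Figure D3:**
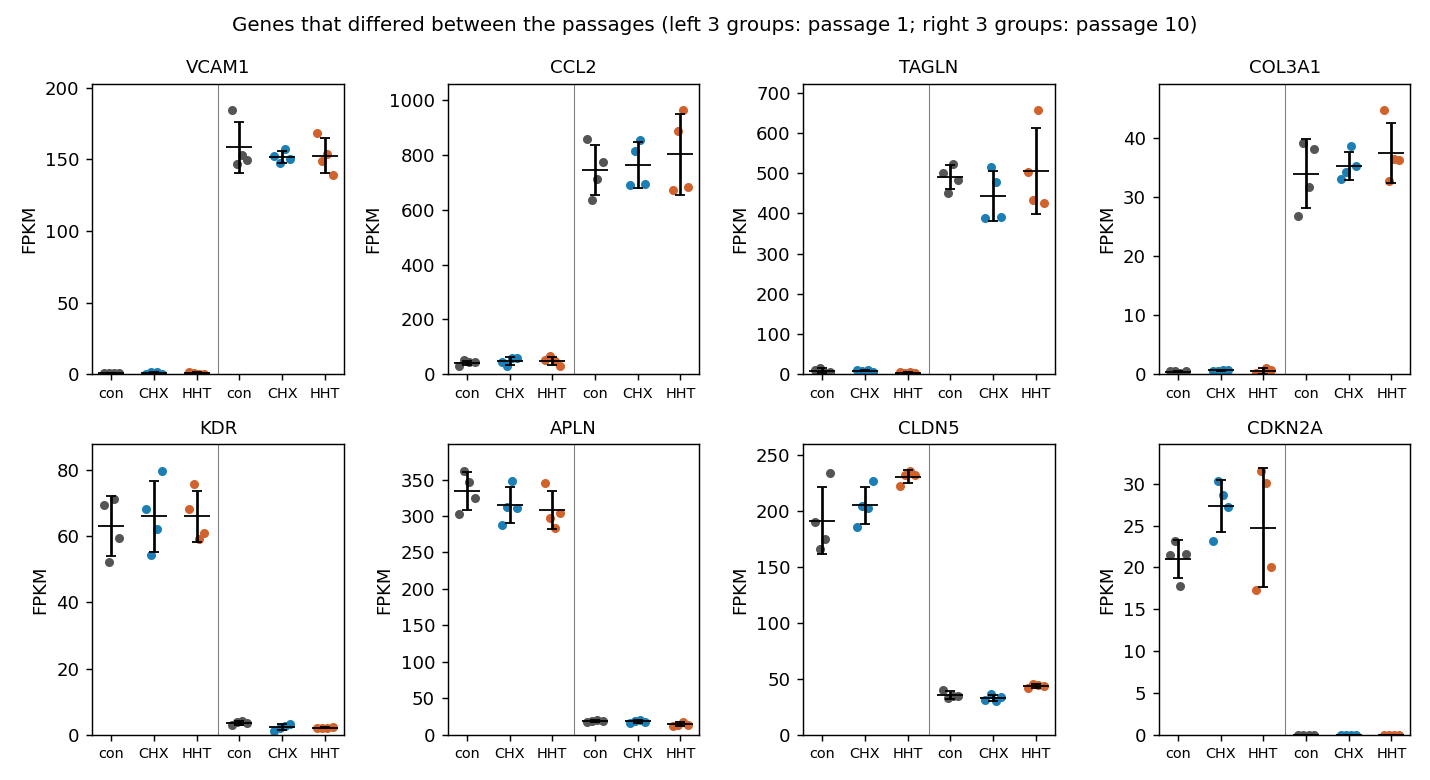
FPKM of 8 genes in each library at passage 1 and passage 10 for control (con), cycloheximide (CHX) and homoharringtonine (HHT); points are libraries, dashes means and bars SD (n = 4), and the vertical axes start at 0. In controls VCAM1 lay at 0.844 ± 0.12 FPKM at passage 1 and 158 ± 17.6 at passage 10, and KDR at 63 ± 8.93 and 3.69 ± 0.624.

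Genes of the NF-kB and cytokine response rose together, 18 of 24 higher and 2 lower (the same numbers adjusted over the list alone), with a median of 1.72 (camera adjusted p = 2.12e-15; adjusted p = 5.16e-05 with an estimated correlation). CCL2, a monocyte chemokine (ENSG00000108691, chromosome 17, 34255218 to 34257203), rose from 41.6 ± 8.11 to 745 ± 92.9 FPKM, and TNFSF15, a cytokine that restrains endothelial growth, fell from 10 to 2.27. Leukocyte markers had 8 of 12 members higher and 1 lower (the same adjusted over the list alone; median 1.43, camera adjusted p = 9.75e-05; adjusted p = 0.00194 with an estimated correlation). Of the 23 leukocyte markers on the list, 11 stayed below the filter and were not tested, and a gene could pass it through 1 passage alone. CD14, a receptor of monocytes that endothelium also makes, rose from 0.427 ± 0.538 to 15 ± 3.78 FPKM and LYZ, lysozyme, from 0.807 ± 0.817 to 9.63 ± 2.82, while LAPTM5 fell from 102 to 32.4. Interferon-stimulated genes had 15 of 39 higher and 5 lower (18 and 6 adjusted over the list alone; median 0.43, camera adjusted p = 0.002; adjusted p = 0.144 with an estimated correlation). HLA-E rose from 153 ± 9.3 to 260 ± 12.1 FPKM and GBP1 from 10.2 to 28.4, and IFITM2, which shares sequence with IFITM1 and IFITM3, fell from 139 to 79.6.

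Of 38 pan-endothelial genes 8 were higher and 16 lower (8 and 17 adjusted over the list alone; median -0.36, camera adjusted p = 0.00164; adjusted p = 0.144 with an estimated correlation). CLDN5, a tight junction protein, fell from 192 ± 30.2 to 35.7 ± 3.22 FPKM and MMRN1, multimerin 1, from 689 ± 56.4 to 255 ± 10.1, and EMCN, endomucin, rose from 35.5 ± 12 to 133 ± 3.9. Tip cell and angiogenesis genes had 3 of 30 higher and 19 lower (5 and 19 adjusted over the list alone; median -1, camera adjusted p = 9.6e-11; adjusted p = 0.00194 with an estimated correlation). MMP1, a collagenase, fell from 1250 ± 98.1 to 127 ± 6.85 FPKM and APLN, apelin (chromosome X, 129645259 to 129654937), from 334 ± 25.6 to 18.9 ± 0.854, while ADAMTS1 rose from 16.8 to 83.8. Of the 30 genes on this list, 19 stand on another list as well.

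Arterial and Notch genes had 5 of 20 higher and 6 lower (6 and 6 adjusted over the list alone), with a median of -0.25, a mean of 0.03 and a downward camera test (adjusted p = 0.958). NRP1, a co-receptor of VEGF, fell from 116 to 22 FPKM, CXCR4 was at 12.5 ± 2.16 and listed at 0 at passage 10, and the gap junction gene GJA4 rose from 0.543 to 19.6. Venous and lymphatic genes had 2 of 13 higher and 5 lower (the same adjusted over the list alone; median -0.62, camera adjusted p = 0.732). NRP2 fell from 124 to 21.9 FPKM and IL33, a nuclear cytokine, rose from 1.32 to 21.4, while CCL14 was at 1.42 ± 0.999 and listed at 0 at passage 10, a call that ended without control passage 1 replicate 1 (0.0604). Flow-responsive genes had 7 of 17 higher and 4 lower (7 and 5 adjusted over the list alone), with a median of -0.2, a mean of 0.1 and an upward test (camera adjusted p = 0.939). CYP1B1 was listed at 0 in passage 1 controls and at 16.7 ± 2.44 FPKM at passage 10, and THBD, thrombomodulin, rose from 17 to 50.4. Coagulation genes had 10 of 24 higher and 7 lower (10 and 10 adjusted over the list alone), with a median of -0.06, a mean of 0.13 and an upward test (camera adjusted p = 0.49). PTGIS, prostacyclin synthase, rose from 1.09 to 60.4 FPKM and EDN1, endothelin 1, from 269 to 536.

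Endothelial-to-mesenchymal transition genes had 9 of 24 higher and 7 lower (10 and 8 adjusted over the list alone; median 0.45, camera adjusted p = 0.00703; adjusted p = 0.0314 with an estimated correlation). COL3A1, a fibrillar collagen (ENSG00000168542, chromosome 2, 188974320 to 189012746), rose from 0.438 ± 0.13 to 33.9 ± 5.79 FPKM, and SPARC, a matrix protein, fell from 3080 to 1530. BMP and TGF-beta targets had 9 of 21 higher and 2 lower (the same adjusted over the list alone; median 0.34, camera adjusted p = 0.000226; adjusted p = 0.00194 with an estimated correlation). CCN2 rose from 660 ± 73.5 to 3300 ± 370 FPKM, BMP4 from 68.9 to 242, and TGFBR2, a TGF-beta receptor, fell from 235 to 136. Extracellular matrix genes had 13 of 32 higher and 10 lower (14 and 10 adjusted over the list alone; median 0.34, camera adjusted p = 0.0452; adjusted p = 0.411 with an estimated correlation). This list was not past camera without control passage 1 replicate 1 (0.0621) or control passage 10 replicate 2 (0.0872) or 4 (0.0619). COL8A1, a short-chain collagen, rose from 76.1 to 493 FPKM.

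Markers of other cell types moved with these lists and in both directions. Below the filter, and so not tested, were 6 of 17 fibroblast, 11 of 17 smooth muscle and 10 of 16 epithelial markers. A gene could pass the filter through 1 passage alone. Of 11 fibroblast markers 4 were higher and 3 lower (the same adjusted over the list alone; median 0.51, camera adjusted p = 0.501). DCN, decorin, rose from 0.722 ± 1.44 to 32.6 ± 9.64 FPKM, and CLEC11A was at 22 ± 3.75 and listed at 0 at passage 10. Smooth muscle markers had 2 of 6 higher and 3 lower (3 and 3 adjusted over the list alone), with a median of -0.01, a mean of 0.58 and a downward test (camera adjusted p = 0.754). RGS5, a pericyte marker also found in endothelium, fell from 436 ± 31.5 to 66.2 ± 13.6 FPKM and SMTN, smoothelin, from 136 to 59.9. Of 6 epithelial markers 5 were lower, over all genes and adjusted over the list alone (median -2.36, camera adjusted p = 3.58e-07; adjusted p = 0.00363 with an estimated correlation). KRT19 (chromosome 17, 41523617 to 41528308) fell from 102 ± 20.7 to 2.22 ± 1.58 FPKM and PERP from 39.3 to 12.2.

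Of 23 cholesterol synthesis and uptake genes 16 were lower and 0 higher (19 and 0 adjusted over the list alone; median -1.02, camera adjusted p = 1.24e-14; adjusted p = 7.71e-06 with an estimated correlation). FDFT1 fell from 203 ± 13 to 60.4 ± 9.39 FPKM and INSIG1, a sterol sensor, from 95.5 to 20.6. Senescence and p53 genes had 6 of 25 higher and 17 lower (6 and 19 adjusted over the list alone; median -0.86, camera adjusted p = 0.0007; adjusted p = 0.0241 with an estimated correlation). CDKN2A, an inhibitor of the cell cycle (chromosome 9, 21967753 to 21995301), was at 21 ± 2.25 FPKM and listed at 0 at passage 10, and CCND2, a cyclin, rose from 1.04 to 28.6. S phase genes had 7 of 31 higher and 0 lower (8 and 0 adjusted over the list alone; median 0.31, camera adjusted p = 0.000513; adjusted p = 0.0241 with an estimated correlation), with TK1, thymidine kinase, up from 61.3 to 153 FPKM. TYMS, thymidylate synthase, rose from 118 to 164, a call that ended without both passage 1 control libraries high in MT-CO1 (adjusted p = 0.0674). G2 and M phase genes had 9 of 35 higher and 0 lower (11 and 0 adjusted over the list alone; median 0.25, camera adjusted p = 7.25e-05; adjusted p = 0.0241 with an estimated correlation), with HMMR up from 16.6 to 48.2 and TOP2A from 44 to 73.2. No member of the list of replication-dependent histones passed, over all 10 or adjusted over the list alone (median -0.33, camera adjusted p = 0.597). H2AJ, on this list although it encodes a histone variant not tied to replication, was at 22 and 18.9 FPKM.

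Of the lists that serve protein synthesis, 23 of 85 ribosomal protein genes were lower and 2 higher (27 and 2 adjusted over the list alone; median -0.33, camera adjusted p = 0.00325; adjusted p = 0.55 with an estimated correlation). RPL3 fell from 698 ± 41.9 to 464 ± 46.9 FPKM and RPL22L1 from 19.9 to 3.93, and these genes have many processed pseudogenes that can share reads. RPLP2 rose from 45.1 ± 6.56 to 80.9 ± 29.8, a call that ended without control passage 1 replicate 1 (adjusted p = 0.0642), control passage 10 replicate 1 (0.0599) or 4 (0.112), or both passage 1 control libraries high in MT-CO1 (0.0501). Translation factors had 10 of 39 lower and 1 higher (the same adjusted over the list alone; median -0.17, camera adjusted p = 0.0317; adjusted p = 0.411 with an estimated correlation). The list was not past camera after median-of-ratios scaling (0.167), without PTP4A2 and SENP3 (0.0953), without both passage 1 control libraries high in MT-CO1 (0.055) or without control passage 10 replicate 3 (0.0648). EIF5 fell from 234 to 139 FPKM and EIF5A from 307 to 205, and EIF2S2 rose from 18.1 to 30.4, not past the threshold without control passage 1 replicate 1 (0.0572) or control passage 10 replicate 4 (0.0907). Among snoRNA hosts and decay targets 5 of 26 were lower and 0 higher (the same adjusted over the list alone; median -0.3, camera adjusted p = 0.319), SNHG17 falling from 21 to 7.77 and SNHG3 from 9.77 to 3.68.

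Mitochondrially encoded transcripts had 6 of 15 lower and 0 higher (the same adjusted over the list alone; median -0.38, camera adjusted p = 0.00605; adjusted p = 0.444 with an estimated correlation). MT-ATP6 fell from 396 ± 17.3 to 260 ± 11.8 FPKM and MT-CO3 from 792 ± 30.2 to 427 ± 93.8; without both passage 1 control libraries high in MT-CO1 the list had an adjusted p of 0.0801. Nuclear oxidative phosphorylation genes had 7 of 34 lower and 0 higher (8 and 0 adjusted over the list alone; median -0.17, camera adjusted p = 0.146), UQCRC2 falling from 129 to 85.2 and NDUFB8 from 43.1 to 22.9. Glycolysis and hypoxia genes had 1 of 32 higher and 12 lower (1 and 14 adjusted over the list alone; median -0.32, camera adjusted p = 0.00605; adjusted p = 0.168 with an estimated correlation). PKM, a glycolytic kinase, fell from 822 to 507 FPKM, ADM, adrenomedullin, from 29.5 to 7.88, and ENO2 rose from 9.82 to 23.5. Heat shock genes had 7 of 15 lower and 0 higher (the same adjusted over the list alone; median -0.27, camera adjusted p = 0.00111; adjusted p = 0.105 with an estimated correlation), with HMOX1, heme oxygenase 1, down from 59.9 to 4.1 and HSPB1 from 604 to 372. Unfolded protein response genes had 4 of 19 higher and 3 lower (5 and 4 adjusted over the list alone), with a median of -0.05 and an upward test (camera adjusted p = 0.992). HSPA5, a chaperone, rose from 475 to 575 FPKM and HERPUD1 from 72 to 116, and PDIA4 fell from 278 to 203.

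Integrated stress response genes had 4 of 22 higher and 6 lower (the same adjusted over the list alone), with a median and a mean of -0.13 and an upward test (camera adjusted p = 0.958). STC2, a secreted glycoprotein, fell from 27.9 to 1.64 FPKM, DDIT4, an inhibitor of mTOR signalling, from 45.7 to 18.6, and WARS1, a tRNA synthetase, rose from 159 to 393. Immediate early genes had 6 of 24 higher and 6 lower (6 and 7 adjusted over the list alone), with a median of -0.04, a mean of 0.18 and an upward test (camera adjusted p = 0.496). CCN1 rose from 481 to 952 FPKM and IER2 fell from 39.9 to 17. Over the 30 lists, 18 were past camera, 10 of them with an estimated correlation, 23 past fry and 29 past its mixed test.

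**Figure D4:**
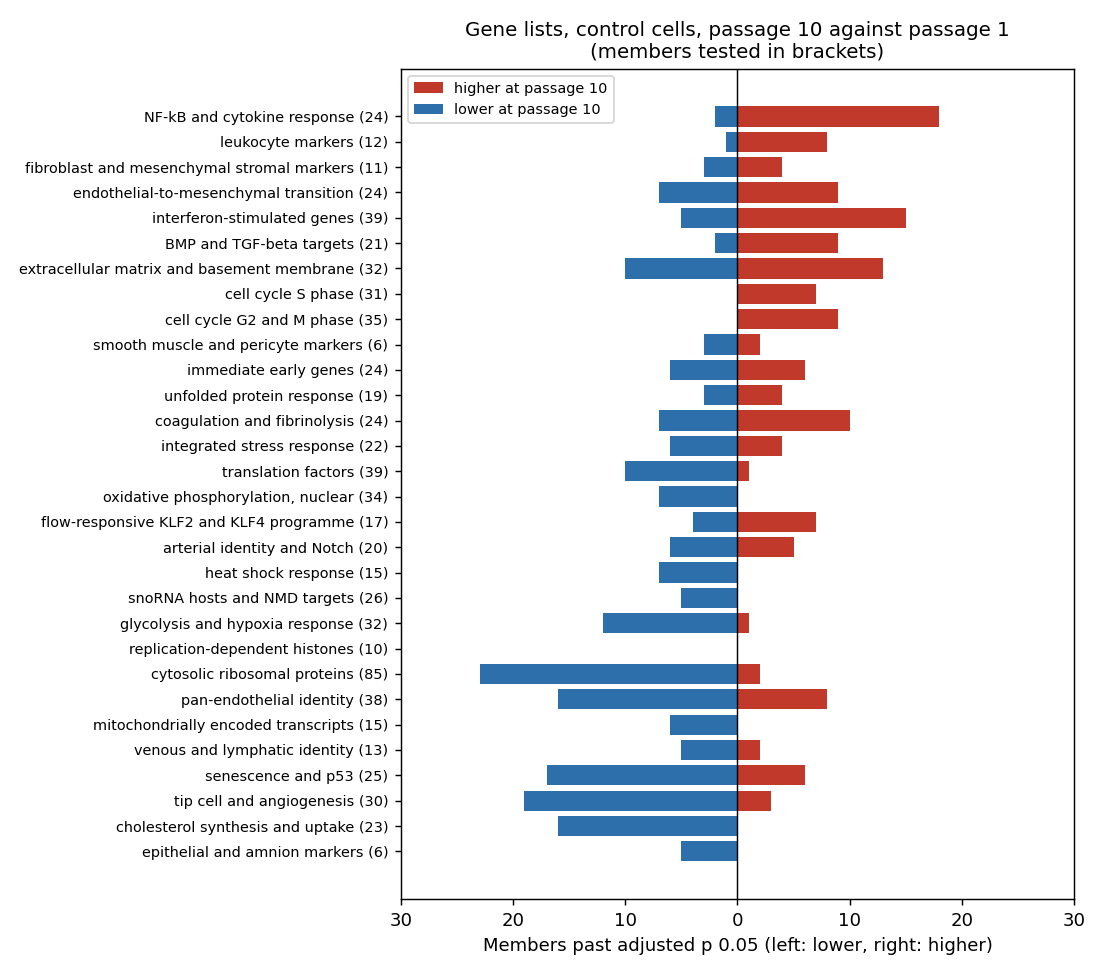
Number of members of each of the 30 gene lists past an adjusted p of 0.05 at passage 10 against passage 1 in control libraries. Bars to the left are lower and to the right higher at passage 10, and members tested stand in brackets. In controls, 18 of 24 NF-kB and cytokine genes were higher and 16 of 23 cholesterol genes were lower.

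With CHX, VCAM1 rose between passage 1 and passage 10 from 0.701 ± 0.611 to 152 ± 4.12 FPKM (6.57 ± 0.25), SULF1 from 9.16 ± 4.24 to 848 ± 65.3 (6.48 ± 0.25) and LITAF from 0.455 to 92.5. CYTL1 was at 112 ± 7.88 and listed at 0 at passage 10, LYVE1 fell by 6.33 on the log2 scale from 108 to 0.428 and CD44 by 5.68 from 176 to 3.35. In limma 3002 genes passed, 1086 higher (36.2%) and 1916 lower, 1565 of them at least 2-fold (704 higher, 861 lower), and 22.3% of genes had non-overlapping libraries (chance 2.86%). After median-of-ratios scaling 2724 passed, 1416 higher (52%) and 1308 lower. NF-kB and cytokine genes had 18 higher and 2 lower of 24 (camera adjusted p = 4.32e-18; adjusted p = 1.76e-05 with an estimated correlation) and cholesterol genes 0 and 18 of 23 (1.57e-14; adjusted p = 8.11e-06 with an estimated correlation). Tip cell genes had 4 higher and 20 lower of 30 (1.93e-10; adjusted p = 0.0026 with an estimated correlation) and senescence and p53 genes 5 and 17 of 25 (0.000507; adjusted p = 0.0222 with an estimated correlation). Ribosomal protein genes had 1 higher and 30 lower of 85 (2.64e-06; adjusted p = 0.255 with an estimated correlation) and pan-endothelial genes 8 and 16 of 38 (0.000362; adjusted p = 0.0912 with an estimated correlation).

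With CHX, 18 lists were past camera, 10 with an estimated correlation. Translation factors (0.0141; adjusted p = 0.255 with an estimated correlation) were not past it after median-of-ratios scaling (0.195) or without PTP4A2 and SENP3 (0.139), nor were glycolysis genes (0.0249; adjusted p = 0.255 with an estimated correlation; 0.129 and 0.0918). Nuclear oxidative phosphorylation genes (0.0141; adjusted p = 0.264 with an estimated correlation) likewise had 0.107 and 0.0774. The glycolysis list also ended without CHX passage 10 replicate 1 (0.0639).

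With HHT, SULF1 rose from 6.72 to 817 FPKM (6.76 ± 0.25), TAGLN from 3.82 ± 1.11 to 505 ± 107 (6.72 ± 0.3) and VCAM1 from 0.632 to 153 (6.65 ± 0.25). CYTL1 was at 109 ± 15.9 and listed at 0 at passage 10, LYVE1 fell by 6.66 from 116 to 0.191 and LIPG by 5.81 from 80.3 to 0.552. In limma 2900 genes passed, 1103 higher (38%) and 1797 lower, 1584 of them at least 2-fold (731 higher, 853 lower), and 21.5% of genes had non-overlapping libraries (chance 2.86%). After median-of-ratios scaling 2742 passed, 1408 higher (51.3%) and 1334 lower. NF-kB and cytokine genes had 17 higher and 2 lower of 24 (camera adjusted p = 3.75e-15; adjusted p = 5.74e-05 with an estimated correlation) and cholesterol genes 0 and 19 of 23 (7.66e-14; adjusted p = 1.15e-05 with an estimated correlation). Leukocyte markers had 8 higher and 1 lower of 12 (4.25e-06; adjusted p = 0.000569 with an estimated correlation) and epithelial markers 0 and 5 of 6 (9.2e-08; adjusted p = 0.00245 with an estimated correlation). Pan-endothelial genes had 8 higher and 16 lower of 38 (0.000267; adjusted p = 0.0801 with an estimated correlation).

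With HHT, 16 lists were past camera, 8 with an estimated correlation. Ribosomal protein genes (0 higher, 14 lower; 0.0191; adjusted p = 0.756 with an estimated correlation) were not past it after median-of-ratios scaling (0.0546) or without HHT passage 1 replicate 2 (0.0955) or HHT passage 10 replicate 1 (0.297). Translation factors (0.0217; adjusted p = 0.364 with an estimated correlation) had 0.212 after that scaling, 0.0978 without PTP4A2 and SENP3 and 0.0732 without HHT passage 10 replicate 4. Glycolysis genes (0.0142; adjusted p = 0.223 with an estimated correlation) had 0.0546 after the scaling.

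Across treatments, 1739 genes passed in all 3 comparisons of passages in the same direction, 706 higher and 1033 lower, of 4362 that passed in at least 1. Between control and CHX, 835 higher and 1234 lower genes were shared, where independent lists would share 92 and 232.4. Between control and HHT the numbers were 804 and 1176 (93.4 and 218), and between CHX and HHT 777 and 1262 (87.8 and 252.3). Fold changes correlated across genes, which are not independent replicates, with r = 0.824, 0.82 and 0.812 in the same order. These comparisons share no libraries, but all 3 set the same cell sources against each other. Their agreement is therefore not a replication of a difference between passages.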

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

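The counts of other splits of the samples were planned before the data were examined, while the share of splits taken as the limit was chosen only after the counts were seen. In groups of 4, a library was called apart where its gap to the nearest of the others made up most of the range of the group. Of 445 groups tested, over 148 genes and measures of the libraries, 41 had a library apart. A chance rate of about 1 in 20 gives 22.2, but that rate cannot be used to judge the 41. SAP30BP, PTGES3P1, SPACA6 and CKB were included because they passed without a library that was then found apart. In other groups, such as LYVE1 and FAP with HHT at passage 10, a single library had any reads, which by itself sets it apart. Whether more libraries were apart than by chance stays undecided.

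Among measures of whole libraries, control passage 1 replicate 1 had an implied depth of 797000 reads (others 1030000 to 1040000), and control passage 10 replicate 1 an FPKM total of 478000 (others 439000 to 445000).

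In control passage 1 libraries, replicate 1 was apart in VCAM1 at 1.02 FPKM (others 0.78 to 0.79) and in EIF5 at 264 (219 to 226). Multiplied by implied depth, VCAM1 was nearly equal in all of these libraries, so its gap follows from the lower depth of replicate 1. Replicate 2 was apart in PTGIS at 2.21 (0.678 to 0.727), CXCR4 at 9.31 (13.1 to 13.9) and TOP2A at 47.1 (42.7 to 43.2). Replicate 3 had CKB at 1.85 FPKM where the others were listed at 0. Replicate 4 was apart in THBD at 19.7 (15.7 to 16.3) and in DCN at 2.89, listed at 0 in the others.

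In control passage 10 libraries, replicate 1 was apart in VCAM1 at 185 FPKM (147 to 153), EIF5A at 236 (193 to 197), EMCN at 139 (131 in the others), TYMS at 184 (157 to 158) and GBP1 at 25.7 (29.1 to 29.5). It was also apart in SAP30BP at 88.9 (45.8 to 49), and in G0S2 at 1.7 with the others listed at 0. Replicate 2 was apart in STC2 at 4.69 (0.385 to 1.08), and in PTGES3P1 at 5.7 with the others listed at 0. Replicate 4 was apart in SULF1 at 864 (919 to 922), EIF2S2 at 45.3 (24.4 to 27), ENO2 at 13.2 (25.6 to 28), H2AJ at 35.4 (11.9 to 14.3) and NUBPL at 10.3 (13.6 to 14.1).

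In CHX libraries at passage 1, replicate 2 had ATP2A3 at 0.211 and LITAF at 1.82 FPKM, both listed at 0 in the others. At passage 10, replicate 3 with CHX was apart in NUBPL at 4.58 (3.49 to 3.59), NAGLU at 31.9 (24.7 to 25.3) and GTF2H3 at 24.8 (20.4 to 20.8). Replicate 1 with CHX had GSTM2 at 2.56 and CLEC11A at 1.16, listed at 0 in the others.

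In HHT libraries at passage 1, MT-CO2 was at 697 FPKM in replicate 1 (608 to 619), LIPG at 95.3 in replicate 2 (74.4 to 75.9) and USP7 at 12.1 in replicate 3 (3.8 to 5.08). Replicate 4 had MED18 at 6.38 (3.81 to 4.21), HLA-E at 153 (177 to 179) and CKB at 0 (3.78 to 4.43). At passage 10, INO80 was at 14.1 in replicate 2 with HHT (10.9 to 11.2), and FAP was at 0.928 in that library and listed at 0 in the others. LYVE1 at 0.762 and SPACA6 at 1.47 were above 0 in replicate 3 with HHT alone.

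As a difference between groups, the response of mitochondrially encoded transcripts to HHT differed between passages in camera with the preset correlation (adjusted p = 0.000517), and not with an estimated correlation (0.947) or in fry (0.981).

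For the comparisons of passages, a chance assignment of these libraries to the passages can be excluded at the level of 1 split in 35. A chance difference between the cell preparations cannot be excluded in this way, since each passage came from 1 source. In splits that mix the passages, their difference enters the spread within groups, which keeps those counts low. The real split gave 2811 genes in controls against at most 1 in the other splits, 3002 with CHX against at most 2, and 2900 with HHT against at most 2, so that 1 of the 35 splits, the real one, reached each count. For HHT against control at passage 10 chance cannot be excluded. HHT gave 1 gene there, 17 of 35 splits gave at least as many and the highest other gave 7, several times the real count. This may point to a structure among these samples, which was not tested. In the other comparisons of inhibitors the real count was 0, which any split reaches, so that the splits say nothing about chance. CHX gave 0 at passage 1, where another of the 35 splits gave 3, and 0 at passage 10, where another gave 4, and HHT gave 0 at passage 1, where another gave 4. With 100 drawn splits, HHT against CHX and the CHX interaction gave 0, with a highest other of 2 each. The HHT interaction also gave 0, but 1 other split gave 31 genes. This too may point to a structure of the samples, which was not tested.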

How the results depend on the processing

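Named genes and lists were recomputed under the alternatives that apply to them; scaling by median of ratios, leaving out PTP4A2 and SENP3, library weights and leaving out both passage 1 control libraries high in MT-CO1 were chosen after seeing the data. Lists were not run with another pseudocount, filter, fold-change limit, model of the compared groups alone or library weights. Leaving out libraries covers the comparisons that use them, and a gene removed by a filter has no value there. Of 464 calls of named genes, 305 passed in every setting run for them and 159 were lost somewhere, most often when a log2 fold change of at least 1 was also asked for; 10 of 316 others passed somewhere and none turned direction. Of 61 list calls, 28 held in every setting run for them and 33 were lost somewhere, and 25 of 239 others passed somewhere. With fry, the arterial and Notch list took the direction opposite to camera with CHX (adjusted p = 0.0405) and with HHT (0.0182) between passages. The cause of changes was not tested unless stated.

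Comparisons of passages gave 1979 to 3043 called genes over settings that asked for no fold-change limit, 1979 being the count in controls without both libraries high in MT-CO1, where fewer libraries were fitted. With an added 2-fold limit the counts were 1552 in controls, 1565 with CHX and 1584 with HHT, and 0 for HHT against control at passage 10. That HHT count of 1 was also 0 with no filter, in a model of the compared groups alone and with library weights. It was 3 after median-of-ratios scaling and 3 without PTP4A2 and SENP3 (MT-ATP6, MT-CO2 and MT-ND4 in both), and the adjusted p of MT-ATP6 ranged from 0.00093 to 0.503. HHT against CHX had 3 genes after median-of-ratios scaling (MT-ND4, MT-CYB and SPACA6) and 4 without PTP4A2 and SENP3 (MT-RNR2 in addition). CHX at passage 1 gave 2 genes with a pseudocount of 0.1 and no filter (ATP2A3 and LINC01605, adjusted p = 0.039 each) and 1 with library weights (LINC01605). HHT at passage 1 gave 1 with library weights (LINC01605) and 1 without both libraries high in MT-CO1 (TAGLN, -1.53, adjusted p = 0.0101). The CHX interaction gave 1 gene with a stricter filter (IDE, adjusted p = 0.0456), where fewer genes were tested. These few genes were named after their values were seen.

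Leaving out each library in turn gave 0 to 1 genes for CHX at passage 1 (MT1A without CHX passage 1 replicate 1), 0 to 2 for CHX at passage 10, 0 to 2 for HHT at passage 1, 0 to 4 for HHT at passage 10, 0 to 2 for HHT against CHX, 0 to 1 for the CHX interaction and 0 in every refit of the HHT interaction. Between passages it gave 2454 to 2641 genes in controls, 2489 to 2769 with CHX and 2481 to 2781 with HHT.

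Replicate numbers did not pair the samples. Deviations of same-numbered libraries within a passage correlated at -0.071 to 0.03, and no number had all its correlations above 0.1. Only 2 of 24 libraries correlated best with a library of their own number in another group of the passage, a hint from the data and not from the design. With the replicate number as a block shared by both passages, the counts between passages were 2738, 2937 and 2845. With separate blocks within each passage, the count was 0 for HHT against control at passage 10 (MT-ATP6 limma adjusted p = 0.122). It was also 0 in the other comparisons of inhibitors and in both interactions. Of the calls of named genes, 11 were not made with the blocks within passages, which were also used for the lists. Under these blocks the ribosomal protein list passed camera in the CHX interaction (0.0415), and they changed the call of no other list there.

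Other size factors from count tools, a second count-based test and filters on counts or CPM, all listed beforehand, were not run since the files hold no counts. The pseudocount and filters on FPKM stood in their place. Depth limits genes of a few FPKM most, since 1 read on a transcript of 2000 bases is worth up to 0.724 FPKM.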

Other observations

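Several markers of other cell types, each over 12 libraries per passage with all treatments together, were low at both passages. COL1A1 was at 0.561 ± 0.803 FPKM at passage 1 and 2.29 ± 1.98 at passage 10, THY1 at 0.369 ± 0.808 and 0.536 ± 0.779, PDGFRA at 0.307 ± 0.376 and 0.065 ± 0.176, and COL6A3 at 0.0253 ± 0.0594 and 0.088 ± 0.143. COL1A2 was at 8.95 ± 2.41 and 11 ± 3.89. PTPRC, the CD45 antigen of leukocytes, was at 0.148 ± 0.512 and 1.82 ± 1.05 FPKM, and TYROBP and CD68 were listed at 0 at passage 1 and at 0.45 ± 1.05 and 0.186 ± 0.463 at passage 10. CD14 was at 0.799 ± 0.681 and 15.1 ± 4.63 and LYZ at 0.269 ± 0.583 and 11.3 ± 3.54. EPCAM, an epithelial adhesion molecule, was at 1.01 ± 1 and 0.15 ± 0.519 FPKM, where KRT19 was at 104 ± 13.8 and 1.88 ± 1.09.

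The tests of the 3 patterns that follow were all chosen only after the patterns were seen.

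PTP4A2 (chromosome 1, 31906421 to 31944856) and SENP3 (chromosome 17, 7561875 to 7571969) led every library in a ratio of 1.59 to 1.74. Separate expression of both genes is argued against by the SD of their log2 ratio, 0.033 over 24 libraries, below the lowest of 153 pairs of other leading genes (0.085). A candidate explanation is reads of a repeat of 25 bases that transcripts of both hold: 2 of 88 other genes with the repeat, PSMD1 and SRGAP1 (r = 0.89 each), and 0 of 13555 without it followed PTP4A2 with r above 0.8 (one-sided Fisher's exact p = 4.1e-05). That limit was set after the correlations were seen, the highest gene without the repeat reached 0.73, 86 of the 88 stayed below, and a rank-sum test over all of them gave p = 0.58. No biological explanation was tested.

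MT-CO1 was at 339.8, 328.4, 1635 and 1455 FPKM in control passage 1 replicates 1 to 4, and at 251 to 555 in the 20 libraries of the other groups. More mitochondrial RNA in some libraries is argued against, since the other 14 mitochondrial transcripts summed differed by 1.1-fold and the most variable of 13 by 1.76-fold, against 4.98-fold for MT-CO1. For reads shared with nuclear copies, 48 annotated copies together reached 0.63 FPKM in these libraries. This cannot decide the question, since how shared reads were assigned is not given and all of them may have gone to MT-CO1. The cause stays open, and no biological explanation was tested.

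Stromal and matrix genes were higher at passage 10, as a group of 10 chosen after their values were seen (TAGLN, COL3A1, DCN, MGP, ELN, COL8A1, EFEMP1, SULF1, CDH11 and FBLN5). Scaling of the libraries is argued against by its size, since the median-of-ratios factors lay between 0.92 and 1.129, far below these changes. All 10 passed after that scaling, with a smallest log2 fold change of 2.79. Those calls add no support, since factors of that size could not end the calls of genes chosen for large rises. Stromal cells rich in COL1A1 and COL1A2 are argued against among the passage 10 cells. Both genes summed rose by 3.8 ± 1.5 FPKM (SE, 12 against 12 libraries) where COL3A1 rose by 35 ± 1.3. Stromal cells low in both genes were not tested. FAP, TBX18 and CLEC11A, 3 of the 11 stromal markers tested, fell in all 3 treatments, while 4 (LUM, DCN, COL3A1 and FBLN1) rose in all 3, and 6 of these 11 markers stand on another list too. A fall shows a loss of what passage 1 cells made, and cannot tell whether stromal cells are among the passage 10 cells. Stromal cells low in COL1A1 and COL1A2, a change of the endothelial cells with passage and a difference between cell sources stay open. The change with passage and the difference between sources cannot be told apart, because each passage came from 1 source.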
